A study of Mus musculus with 96 samples.

How the data were processed

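The samples are 96 single cells from the bone marrow of C57BL/6 mice of 1 genotype, ThPOK-/-, in which Zbtb7b, the gene of the transcription factor ThPOK, is knocked out. Per the labels, the cells were enriched for CD117 on magnetic beads, sorted as granulocyte-monocyte progenitors (GMP), and captured on a Fluidigm C1 chip, with SMARTer cDNA and Nextera XT libraries. The labels name no animal, so the 96 cells were treated as 1 sample and cells were not counted as replicates of the genotype. The series also covers wild-type cells, which were not analysed here because no label maps them, and no comparison between genotypes was made. Cell names carry a label number, 078 or 079, with 48 cells each. Its meaning is not given, and it was used only to repeat results within each set of cells.

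Expression values were deposited by the authors as log2 values for 23955 genes, named RSEM TPM (transcript abundance scaled to a fixed sum per cell) in the deposited table. Raising 2 to each value and subtracting 1 gave a sum of 1e+06 in every cell, so the deposited log2 values were read as log2(TPM + 1), and every log2 value given here is on that scale. Splicing values were deposited by the authors as fractions from 0 to 1, the proportion of junction reads that take a given junction (percent spliced in, PSI), for 80855 events. A deposited annotation by the authors gives a state name for 69 of the 96 cells, and 27 cells have none. How the states were made is not stated. Per the submitters' processing notes, the genome builds mm9 and mm10 and the tools Bowtie2, RSEM and STAR were used, with no versions and no word on which served which table. The splicing data hold 1142 columns, and the state annotation 511 entries, for cells that no label maps, and these were not used here, nor was the table's column of PSI differences.

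Reads per cell are not given. TPM keeps no depth and the PSI fractions come without junction read counts, so depth is unknown for both, and the number of genes at a TPM of 1 or more stands in for it. Clopper-Pearson intervals at the 95% level are given for shares of cells, and in places for shares of splicing events or PSI values. For cells they cover only the counting of cells in this 1 sample, and not differences between animals. Reads are PCR copies without molecular identifiers, so they are not independent molecules. A value of 0 in these tables is described as listed at 0, because even Tbp, which every cell uses, was under a TPM of 1 in most cells.

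Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9. Cells with at least 1000 genes at a TPM of 1 were kept, which kept all 96. A gene counted as detected in a cell at a TPM of 1 or more. No doublet caller was run, since it needs counts, and doublets are weighed in the closing section. The highest Pearson r of log2 values between any pair of cells was 0.685, and 0 pairs of cells were identical.

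The following were fixed before the data were examined: the gene lists, the designs, most of the other settings tried and the rule for named genes. The 18 expression lists hold 230 distinct genes: primary granule (12), secondary granule and neutrophil (13), monocyte (15), dendritic cell (12), eosinophil (8), mast cell and basophil (8), stem and multipotent (16), erythroid and megakaryocyte (16), B lymphoid (12), T and NK (12), stroma and endothelium (8), myeloid transcription factors (22), S phase (19), G2/M phase (20), immediate early and stress (12), interferon response (12), growth factor receptors (14) and housekeeping (10). A list of 34 genes was fixed for splicing. For each list the share of cells with each member was computed, and the list's median share was placed among 10000 random lists of equal size. A list score is the mean log2 value of its members in a cell. Named genes are members of these lists, up to 10 genes with the highest and 10 with the lowest rho per gene-wide correlation among those past the threshold and of the same sign in both label numbers, the 10 genes of highest mean, splicing events in the splicing list, and the 10 intermediate events with values in the most cells.

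Cells were clustered with Ward's method on 10 principal components of the 500 most variable genes, detected in at least 10% of cells, with the number of clusters from 2 to 6 set by the mean silhouette. The clusters were planned because the labels describe no annotation. Since a deposited annotation of states was found, gene lists are described by state, and the clusters are given beside it.

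Relations between measures across cells were computed as Spearman's rho and Pearson's r with two-sided permutation tests of 100000 permutations, whose smallest possible p is 1e-05. Their p-values come from shuffling cells of this 1 sample and say nothing of other animals. Families were Irf8 with Gfi1 (alone), 8 pairs of list scores with genes in both lists left out, and, for each of 5 anchor genes, every other gene detected in at least 20% of cells, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. Because cells fall into states, pooled values are given with values within IG2 and Multi-Lin-1, and for list scores also within proNeu-1, except where a state has too few cells with the gene. The planned permutation test of genes detected between label numbers would count cells as replicates, so only means and SD are given. The gene-wide correlation was tested on simulated data over 5719 genes: 36% of genes planted at a latent correlation of 0.3 with Elane were recovered, 98% at 0.5, 100% at 0.7 and 94% at -0.5, with 9 of 5519 unrelated genes called and 0 of 5719 when nothing was planted. In simulated cells, clustering put all 30 planted cells together and 0 of 66 others with them. The planted cells shared a large upward shift in many genes, so this says nothing of how well weaker differences between cells are separated. Each gene was shuffled across cells on its own, so the simulated data hold no states and no differences in genes detected. The rates therefore do not cover relations that arise through these.

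Splicing events with a value in at least 20 cells were summarised by mean and SD, and called intermediate at a mean from 0.1 to 0.9. Event coordinates are as deposited. Their build is not named, and 99.4% of 86196 junction ends fall on exon ends of the GENCODE M21 annotation (GRCm38, that is mm10), against 0.632% after a shift of 100 bp. These ends are of examined junctions whose deposited names carry no added coordinate. Entries that span an exon-intron boundary were left out, so the share does not cover all events. Gene coordinates are from the same annotation. Events of a gene overlap or are reciprocal, so they are not independent.

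Alternatives, whose effects are in the closing section, were other detection thresholds (above 0, TPM of 5), no cell filter or at least 2000 genes per cell, Pearson's r in place of rho, a pseudocount of 10, regression of each gene on genes detected and label number, other gene filters, only cells with Irf8 or Gfi1, other clustering settings, and other minimums and bounds for PSI. Added after seeing the data were a TPM of 30, cells with a deposited state only, and leaving out the cells in which 1 gene holds 5% of TPM.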

Results

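RNA of 96 single ThPOK-/- GMP was measured as expression per gene and as PSI per splicing event. The number of genes detected per cell ran from 1019 to 5203, with a median of 3353. It was 3365 ± 802 (mean ± SD, n = 48) in cells numbered 078 and 3229 ± 920 (n = 48) in those numbered 079, a difference smaller than the SD. The authors placed 31 cells (32.3%) in the state IG2, 26 (27.1%) in Multi-Lin-1 and 12 (12.5%) in proNeu-1, and 27 (28.1%) have no state. Both label numbers held cells of each, 16 and 15 of IG2, 11 and 15 of Multi-Lin-1, 6 and 6 of proNeu-1, and 15 and 12 without a state. Median genes detected were 3940 in IG2, 2950 in Multi-Lin-1, 4127.5 in proNeu-1 and 2613 in cells without a state. All values below are from 1 sample of 1 genotype, and SD is over cells.

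The first question was whether transcripts of the targeted gene were found. Zbtb7b (ENSMUSG00000028042, chromosome 3, 89377644 to 89394776 on GRCm38, minus strand) was at a TPM of 1 or more in 2 of 96 cells (2.08%, interval 0.253 to 7.32%). It was above 0 in 7 cells (7.29%), with a highest TPM of 2.12. At a TPM of 5 it was found in 0 of 96 cells, which allows a share of up to 3.77%. The labels do not give the deleted exons, and no wild-type level was analysed here, so the low value checks the label only as far as transcripts of the whole gene go. The splicing table has 0 events for this gene.

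The second question was which lineage programmes these progenitors express. Primary granule genes led: 9 of 12 were detected in at least 50% of cells, among them Mpo (myeloperoxidase) in 100%, the protease genes Elane in 95.8%, Prtn3 in 90.6% and Ctsg in 86.5%, and Ms4a3, a marker of granulocyte and monocyte progenitors, in 75%. At a TPM of 30 the shares were 78.1% for Mpo, 56.2% for Elane, 76.04% for Prtn3, 69.8% for Ctsg and 61.5% for Ms4a3, so part of the Elane detection is at low values. Hp (39.6%), Prss57 (43.8%) and Fcnb (8.33%) were found in fewer cells. Genes of later neutrophils were rare. Of 13 secondary granule and neutrophil genes 0 reached 50% of cells, with S100a8 and Cebpe, a regulator of late granule genes, in 29.2% each, and Ltf (lactoferrin) and Camp listed under a TPM of 1 in every cell. Of 15 monocyte genes 0 reached 50%: Ly6c2 was detected in 43.8%, Irf8, a regulator of monocyte and dendritic cell fate, in 8.33%, and Csf1r, the M-CSF receptor gene, in 4.17%.

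Of 8 mast cell and basophil genes 4 were detected in at least 50% of cells, namely Hdc (histidine decarboxylase, 65.6%), the transcription factor gene Gata2 (63.5%), Cpa3 (59.4%) and Mcpt8 (53.1%). Stem and multipotent genes followed with 4 of 16, Cd34 (76%), Gpr56 (71.9%), Kit, the stem cell factor receptor gene (69.8%), and Angpt1 (59.4%). The erythroid and megakaryocyte list had 1 of 16, Car2 (64.6%), with Gata1, the erythroid and mast cell regulator, in 36.5% and Klf1 in 14.6%. Counts were 1 of 12 for dendritic cells (Tcf4, 50%), 0 of 8 for eosinophils (Prg2 36.5%), 0 of 12 for B cells (Cd79b 26%), 0 of 12 for T and NK cells (Cd3d 8.33%) and 1 of 8 for stroma and endothelium, where Lepr was detected in 91.7% of cells but at a TPM of 30 in 3.12%. Among myeloid transcription factors, 9 of 22 reached 50%, with Myb in 96.9%, Myc in 78.1% and Spi1, which encodes PU.1, in 54.2%, against Gfi1, a repressor active in granulocyte fate, in 21.9% and Cebpa in 20.8%. Growth factor receptors gave 4 of 14, with Ifngr1 in 91.7% and Csf3r, the G-CSF receptor gene, in 55.2%. Housekeeping genes gave 9 of 10. At a TPM of 30 the counts were 1 of 8 for mast cells and basophils (Hdc 56.2%, against 49% for Gata2, 49% for Cpa3 and 34.4% for Mcpt8), 3 of 16 for stem genes, 0 of 16 for the erythroid list, 0 of 12 for dendritic cells, 4 of 22 for myeloid transcription factors, 1 of 14 for growth factor receptors and 9 of 10 for housekeeping genes. The mast cell and basophil count at a TPM of 1 was 4 in cells numbered 078 and 3 in 079, where Mcpt8 was detected in 41.7% against 64.6%. Random lists of genes set a low bar, since the secondary granule list, with a median share of 1.04%, lay at percentile 51.8 of them. The primary granule, S phase, G2/M, immediate early and housekeeping lists lay at percentile 100, myeloid transcription factors at 99.99, mast cell and basophil at 99.9, stem at 99.56 and growth factor receptors at 97.51. Raising the threshold to a TPM of 30 left 38 of the 64 list genes that reached 50% of cells.

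Across the authors' states, granule genes differed by many log2 units. Elane averaged 14.91 ± 0.41 (SD, n = 12) in proNeu-1 and 13.33 ± 1.52 (n = 31) in IG2, against 3.58 ± 2.09 (n = 26) in Multi-Lin-1 and 4.20 ± 2.65 (n = 27) in cells without a state. Mpo averaged 14.52 ± 0.56, 13.64 ± 0.78, 8.05 ± 3.71 and 6.94 ± 4.57 in the same order. Gata2 went the other way, 1.68 ± 2.54 in proNeu-1 and 1.99 ± 2.74 in IG2 against 7.23 ± 2.69 in Multi-Lin-1 and 6.88 ± 4.19 in cells without a state. The erythroid and megakaryocyte score was 0.22 ± 0.19 in proNeu-1, 0.37 ± 0.42 in IG2, 1.11 ± 0.66 in Multi-Lin-1 and 1.62 ± 0.98 in cells without a state, and the stem and multipotent score was highest in Multi-Lin-1 (2.32 ± 0.68) and lowest in proNeu-1 (1.08 ± 0.32). Cd34 averaged 7.53 ± 2.28 in IG2 and 3.60 ± 3.23 in proNeu-1. Cebpe averaged 4.65 ± 2.66 in proNeu-1 and 0.03 ± 0.16 in Multi-Lin-1, and Gfi1 2.36 ± 2.89 in IG2 and 0.11 ± 0.57 in Multi-Lin-1. No test was made between states, because cells are not replicates and the states presumably rest on the same expression values.

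**Figure D1:**
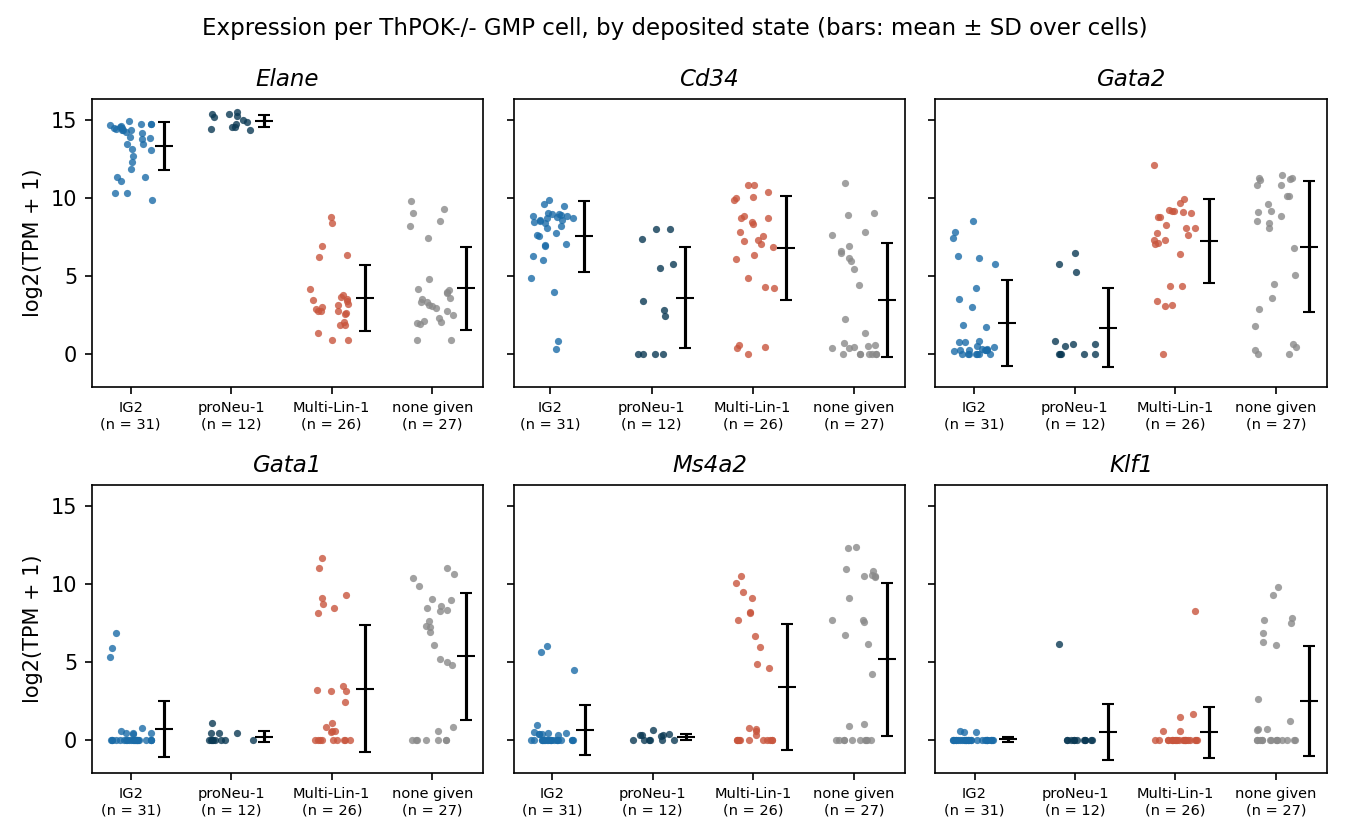
Log2(TPM + 1) of Elane, Cd34, Gata2, Gata1, Ms4a2 and Klf1 in each of 96 cells, grouped by the authors' state, with 1 point per cell and bars for the mean ± SD over cells. Elane averages 13.33 in IG2 and 14.91 in proNeu-1 against 3.58 in Multi-Lin-1, while Gata2 averages 7.23 in Multi-Lin-1 and 1.68 in proNeu-1.

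Clustering without the states gave 2 clusters (mean silhouette 0.262). Cluster 1 held 36 of 96 cells (37.5%, interval 27.8 to 48%), 18 of each label number, of which 25 were IG2 and 11 proNeu-1. Its leading genes were Elane, Ms4a3, Gstm1, Alas1 and Anxa3, and 11 of 12 primary granule markers were detected in at least 50% of its cells, so it is called primary granule-like. Cluster 2 held 60 cells, all Multi-Lin-1 cells and all cells without a state among them, and was led by Gata2, Ifitm1, Apoe, Vamp5 and Car2. It was left unnamed, since its 10 leading genes hold 2 markers each of the mast cell and basophil list and of the erythroid list. Among its 20 leading genes the counts were 3 and 2, so leaving it unnamed depends on how many leading genes are taken. The adjusted Rand index of the 2 clusters and 3 states was 0.466 over the 69 cells with a state. Cells without a state were left out of it, and 2 clusters cannot match 3 states in full. With 1000 variable genes, the cluster that took in all 36 of these cells held 72.9% of cells, 16 Multi-Lin-1 cells and 11 without a state among them, and was not named.

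Irf8 and Gfi1 are textbook opponents in the choice between monocyte and granulocyte fate, and the question was whether they exclude each other in single cells. Irf8 was detected in 8 cells and Gfi1 in 21, with both in 2 cells against 1.75 by chance. Across 96 cells rho was 0.0457 (permutation p = 0.647) and r was 0.0476 (p = 0.660). Within label numbers rho was -0.0385 in 078 and 0.179 in 079, and r was -0.110 and 0.288 (unadjusted permutation p = 0.0453 in 079). Within IG2 rho was -0.233 (n = 31). Without the 2 cells farthest from the median of Irf8, rho was 0.102 and r was 0.115. With Irf8 in 8 cells, a relation between the genes was not detectable over all 96 cells.

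Scores of 8 preset pairs of lists were set against each other across cells, and 6 passed the adjusted threshold. The primary granule score went up with the monocyte score (rho 0.575, r 0.538), the S phase score (rho 0.528, r 0.515) and the secondary granule score (rho 0.523, r 0.504), each with p = 1e-05, the smallest that the permutations can give, and an adjusted p of 2.67e-05. Of the 15 monocyte genes 10 were in under 10% of cells, and of the 4 tested against Elane 1, Ly6c2, went up with it (rho 0.642), while Zeb2 (0.220), Psap (0.136) and Ms4a6c (0.0563) did not pass. The primary granule score also went up with the G2/M score (rho 0.413, r 0.333, adjusted p = 0.00014) and down with the stem score (rho -0.234, r -0.233, adjusted p = 0.0291). S phase and G2/M scores went together (rho 0.373, r 0.236, adjusted p = 0.000336). Monocyte scores gave rho 0.144 with dendritic (r 0.138, adjusted p = 0.184) and -0.0342 with stem scores (r -0.0479, adjusted p = 0.743). In cells numbered 078 and 079 the rho values were 0.602 and 0.561 for granule with monocyte, 0.454 and 0.608 with S phase, 0.611 and 0.443 with secondary granule, 0.441 and 0.385 with G2/M, and -0.315 and -0.170 with stem scores. For S phase with G2/M they were 0.471 and 0.336.

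By rho, no pair passed the adjusted threshold within IG2, Multi-Lin-1 or proNeu-1, while by r granule with S phase passed within IG2 (r 0.539, adjusted p = 0.0114). Within IG2 (n = 31), rho was -0.00363 for granule with monocyte, 0.454 with S phase (adjusted p = 0.0912), 0.182 with secondary granule, -0.137 with G2/M and -0.283 with stem scores, and -0.210 for S phase with G2/M. Within Multi-Lin-1 (n = 26) the same pairs gave 0.331, 0.0571, 0.394, 0.411, 0.180 and 0.211. Within proNeu-1 (n = 12) they gave 0.182, 0.671 (permutation adjusted p = 0.162), 0.322, -0.119, 0.503 and 0.147, so that granule with G2/M and granule with stem scores turned in sign. Monocyte with dendritic scores gave -0.117, 0.148 and 0.140 within IG2, Multi-Lin-1 and proNeu-1, and monocyte with stem scores 0.226, 0.175 and -0.119. Without the 2 cells farthest from the median of the granule score, r was 0.521 with monocyte, 0.522 with S phase, 0.499 with secondary granule, 0.315 with G2/M and -0.282 with stem scores, and without those farthest in S phase score it was 0.214 with G2/M. After regression on genes detected and label number, granule with S phase gave 0.0658, granule with G2/M -0.0508, granule with monocyte 0.273 and granule with stem scores -0.449. S phase with G2/M turned to -0.226 by rho (adjusted p = 0.0554) and to -0.269 by r (adjusted p = 0.0163), so the upward relation of these 2 scores is lost there and by r passes in the reverse direction. It was 0.0903 in cells with a state alone, where granule with stem scores gave -0.544.

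The gene-wide search then asked which genes go with a marker of each programme. Elane went with most of the granule programme: Mpo gave rho 0.891, Ms4a3 0.823, Prtn3 0.811, Igsf6 0.803, Ctsg 0.778, Gstm1 0.768, and Alas1, the first enzyme of haem synthesis, 0.764, each at an adjusted p of 0.000304. Genes lower where Elane was high were Tmsb10 (-0.633), Vamp5 (-0.608), Gata2 (-0.601), Apoe (-0.551) and Notch2 (-0.529), with the ribosomal protein genes Rpl32 (-0.538), Rpl21 (-0.520) and Rps7 (-0.509), whose pseudogene copies can share reads. In all 1432 of 5718 genes passed, 1306 upward and 126 downward. All 10 primary granule genes tested went up with it, 10 adjusted over the list alone. Of 18 S phase genes 11 went up, 12 adjusted over the list alone, and of 20 G2/M genes 5, with 5 adjusted over the list alone. Of 3 erythroid genes tested 2 went down, 3 adjusted over the list alone.

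For the genes named next, values within states were smaller in size, and some turned in sign. Within IG2 the rho with Elane was 0.690 for Mpo, 0.637 for Ms4a3, 0.508 for Prtn3, 0.679 for Ctsg, -0.438 for Tmsb10 and -0.304 for Gata2, and within Multi-Lin-1 it was 0.289, 0.400, 0.240, -0.00889, -0.471 and -0.140. Igsf6 gave 0.396 in IG2 and 0.370 in Multi-Lin-1, Gstm1 0.661 and 0.0597, Alas1 0.439 and 0.412, Vamp5 -0.390 and -0.335, Apoe -0.290 and -0.00376, and Notch2 -0.394 and -0.235. The ribosomal protein genes gave -0.192 and -0.0229 for Rpl32, -0.194 and -0.316 for Rpl21, and -0.229 and 0.0126 for Rps7. Within proNeu-1 (n = 12) Ms4a3 (-0.399), Prtn3 (-0.0839), Vamp5 (0.157) and Apoe (0.222) turned in sign. There Mpo gave 0.280, Ctsg 0.301, Igsf6 0.147, Gstm1 0, Alas1 0.0490, Tmsb10 -0.259, Gata2 -0.305, Notch2 -0.497, Rpl32 -0.308, Rpl21 -0.133 and Rps7 -0.0210. For Mpo, rho was 0.913 in 078 and 0.873 in 079, r was 0.787, and without the 2 farthest cells r was 0.777. Regression on genes detected and label number left 141 genes past the threshold, 94 upward and 47 downward, with 9 of 10 primary granule, 0 of 18 S phase and 0 of 20 G2/M genes.

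Gfi1 went with 151 of 5718 genes, 142 upward and 9 downward. Highest were Ly6c2 (rho 0.516, adjusted p = 0.0052), Elane (0.516), Ly6a, which encodes Sca-1 (0.489), Gpc1 (0.481), Tor1b (0.480) and Ly6c1 (0.478), and lowest S100a10 (-0.399), Fyb (-0.390) and Gata2 (-0.390). Ly6a, Tor1b and Ly6c1 were low, with mean log2 values of 1.16, 1.21 and 1.02 and detection in 29.2%, 24% and 25% of cells. Whether Ly6a and Ly6c1 share reads with Ly6c2 was not examined, so they may not be separate results. Of 11 primary granule genes 9 went up, 9 adjusted over the list alone. Within IG2, which holds 15 of the 21 cells with Gfi1, rho was 0.476 for Ly6c2, 0.386 for Elane, 0.430 for Ly6a, 0.227 for Gpc1, 0.412 for Tor1b, 0.408 for Ly6c1, -0.350 for S100a10, -0.164 for Fyb and -0.127 for Gata2. Multi-Lin-1 has Gfi1 in 1 cell, so no value is given there. Within proNeu-1, with Gfi1 in 5 of 12 cells, the same genes gave 0.0261, 0.202, 0.0634, 0.328, 0.104, -0.295, -0.304, 0.220 and -0.297, so that Ly6c1 and Fyb turned in sign. For Ly6c2, rho was 0.563 in 078 and 0.466 in 079, and r was 0.465 and 0.439 without the 2 farthest cells. After regression 48 genes passed, all upward, with 0 of the primary granule genes. The downward calls were all lost there, with S100a10 at -0.234 (adjusted p = 0.233), Fyb at -0.176 (0.437) and Gata2 at -0.0941 (0.757), and also in cells with a state alone, where 36 genes passed, all upward. Ly6c1 lost its call after regression (permutation adjusted p = 0.0520) and in cells with a state (0.0616). Since few cells have Gfi1, its residual may follow genes detected, as that of Irf8 does in the closing section. This was not computed for Gfi1, so the regressed calls are uncertain. By r, Fyb did not pass (-0.295, adjusted p = 0.0861).

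Mki67, which marks cycling cells, went with 257 of 5718 genes, 253 upward and 4 downward. All 19 G2/M genes tested went up, 19 adjusted over the list alone, among them Birc5 (survivin, rho 0.626, adjusted p = 0.00159), Kif11, a spindle motor gene (0.601), and Top2a (topoisomerase II alpha, 0.596). Fbxo5 gave 0.598 and Kif15 0.597, and Notch2 was lowest at -0.378. Of 18 S phase genes 2 went up, 4 adjusted over the list alone. The relation was present within states: Birc5 gave 0.507 in IG2 and 0.683 in Multi-Lin-1, Kif11 0.376 and 0.683, Top2a 0.369 and 0.585, Fbxo5 0.483 and 0.607, Kif15 0.601 and 0.588, and Notch2 -0.288 and -0.386. Within proNeu-1 they gave 0.270, 0.208, 0.239, 0.590, 0.241 and -0.0653. For Birc5, rho was 0.701 in 078 and 0.547 in 079, and r was 0.690 and 0.706 without the 2 farthest cells. After regression 52 genes passed, 14 of the 19 G2/M genes among them, while Notch2 did not (-0.172, adjusted p = 0.729).

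Cd34 went with 3 genes of 5718, all upward: Serpina3g (rho 0.449, r 0.417), Hsd17b12 (0.436, r 0.429) and Meis1, a stem cell transcription factor gene (0.415, r 0.336), each at an adjusted p of 0.0381. An unadjusted p under 0.05 was reached by 467 genes. Within IG2 their rho was 0.363, 0.516 and 0.330, within Multi-Lin-1 0.219, 0.612 and 0.529, and within proNeu-1 0.280, 0.667 and 0.439. All 3 calls were lost by r (adjusted p 0.0762, 0.0762 and 0.250) and after regression on genes detected and label number (adjusted p 0.0858, 0.0858 and 0.366). They were lost as well in cells with a state and with genes in at least 3 cells tested. Irf8 went with 0 of 5719 genes by the permutation test of rho, with 407 at an unadjusted p under 0.05, and with 0 by Pearson's r, with 456.

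Of the 34 genes fixed for splicing, 24 were detected in at least 50% of cells. Splicing was read from 74512 events with a value in at least 1 cell. Of 1151837 values, 52.6% were 0, 41% were 1 and 6.34% lay between. A cell had a median of 11663.5 events, from 112 to 23092. With a value in at least 20 cells there were 19295 events in 2377 genes: 7534 had a mean above 0.9, 9577 below 0.1, and 2184 (11.3%) were intermediate. Among intermediate events, 1767 (80.9%) had at least 80% of cells outside 0.1 to 0.9. This share depended on the minimum of cells, with 90.25% at a minimum of 10 cells and 53.3% at 40. It was 71.4% in cells with a state. Intermediate means were found in 598 of 8067 intron retention events and 594 of 4394 cassette exon events.

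Pkm, the pyruvate kinase gene, mainly used the M2 exon (chromosome 9, 59675568 to 59675734). The junction into it had a PSI of 0.774 ± 0.186 (n = 69 cells) and the junction out of it 0.811 ± 0.138 (n = 69). Junctions of the M1 exon (59675029 to 59675195) had 0.0284 ± 0.0744 (n = 65) and 0.0876 ± 0.0554 (n = 71). The M2 entry junction was at 0.790 in IG2, 0.739 in Multi-Lin-1, 0.792 in proNeu-1 and 0.760 in cells without a state. In Srsf7, a splicing factor gene, skipping of the exon at 80204622 to 80205081 on chromosome 17 had a PSI of 0.522 ± 0.378 (n = 82), with 0.645 ± 0.310 (n = 30) in IG2, 0.558 ± 0.373 (n = 22) in Multi-Lin-1, 0.506 ± 0.381 (n = 10) in proNeu-1 and 0.306 ± 0.408 (n = 20) in cells without a state. No test was made between states. In Tra2b, another splicing factor gene, the skipping junction from 22255117 to 22265741 on chromosome 16 had 0.581 ± 0.414 (n = 69). That of Hnrnpa2b1 from 51464211 to 51465179 on chromosome 6 had 0.245 ± 0.225 (n = 82), that of Mbnl1 from 60613520 to 60615620 on chromosome 3 had 0.715 ± 0.373 (n = 75), and that of Hnrnpd from 99962612 to 99963984 on chromosome 5 had 0.371 ± 0.451 (n = 46).

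The intermediate events with values in the most cells were 7 in Gas5, a host gene of small nucleolar RNAs on chromosome 1 (n = 96), with means from 0.211 to 0.894, a reciprocal pair in Rps28 on chromosome 17 at 0.355 and 0.642 (n = 95), and 1 in Rps18 at 0.323 (n = 94). Only 1 junction end of the Rps18 event falls on an annotated exon end. Pooled over all intermediate events, values between 0.1 and 0.9 were commoner where the gene was high. They made up 4.78% of values at a log2 expression under 2 and 37% at 10 or more. This pooling mixes different genes. Within single events the share averaged 15.4% in the cells with the higher level of the gene and 11.5% in the others. Depth per junction is unknown, so the precision of a single PSI value cannot be given.

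**Figure D2:**
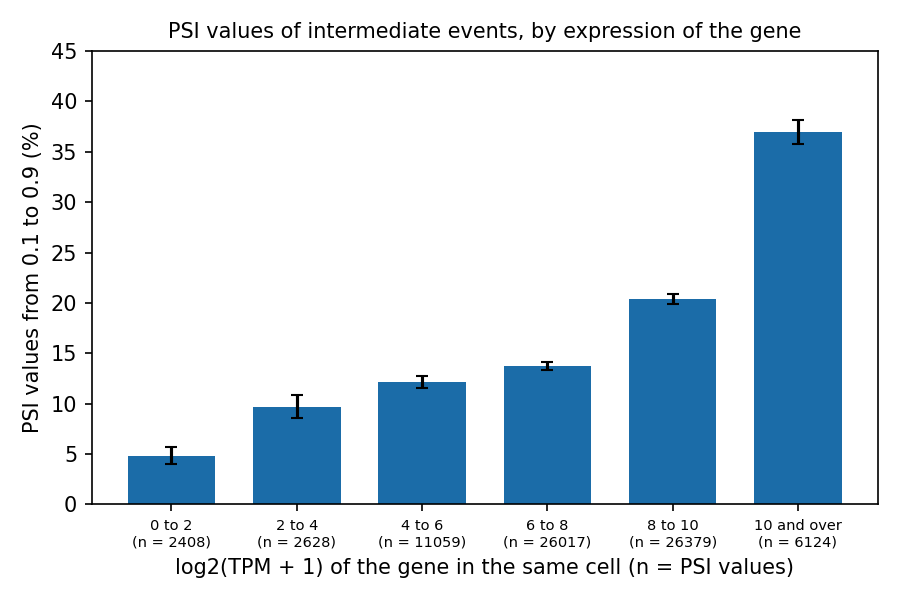
Percent of PSI values of intermediate events that lie between 0.1 and 0.9, by log2(TPM + 1) of the gene in the same cell, with 95% Clopper-Pearson intervals. The share goes from 4.78% at the lowest expression to 37% at the highest. Values are pooled over different genes and events. The intervals count each value as independent, though values of 1 event recur across cells and events of a gene overlap, so they are too narrow.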

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

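The tests in this part were chosen only after the result was seen. Cells without a deposited state lie outside the comparison of states, and they held an erythroid and mast cell signal, which Multi-Lin-1 cells shared in part. Gata1 was at a TPM of 30 or more in 17 of these 27 cells (63%, interval 42.4 to 80.6%). Any presence beyond that of a count of 0 was singled out here, which is no test against other cells. It was so in 10 of 69 cells with a state (14.5%, 7.17 to 25%), and in 26.9% of Multi-Lin-1 cells. The 17 cells split into 10 of label number 078 and 7 of 079. By further genes, 9 of the 27 cells had the erythroid genes Klf1 or Car1 at that level and 15 the mast cell and basophil genes Ms4a2 or Prss34, with both kinds in 1 cell and neither in 4. In Multi-Lin-1 it was 2 and 9 of 26 cells. Other genes of the mast cell and basophil list differed. Gata2 reached that level in 76.9% of Multi-Lin-1 cells against 66.7% without a state, and Cpa3 in 69.2% against 55.6%. Mcpt8 did so in 7.69% against 44.4%, with 50% in proNeu-1.

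At least 3 of the 32 genes of the erythroid, mast cell and basophil, and eosinophil lists were at a TPM of 30 in 24 of these 27 cells (88.9%, 70.8 to 97.6%). Whether fewer genes detected per cell raise this share cannot be told apart from state, since it was 25% in proNeu-1, 45.2% in IG2 and 73.1% in Multi-Lin-1 (52.2 to 88.4%, overlapping), against median genes of 4127.5, 3940 and 2950, and 2613 without a state. Doublets with a granulocyte progenitor cannot be settled by Elane. Its highest TPM in the 24 cells was 621.81, with 0 of 24 at 1000 (upper limit 14.2%) and an IG2 median of 15111.5. A doublet high in Elane may have been placed in IG2 or proNeu-1, where 100% of cells had Elane at a TPM of 30. It would then be missing from the 24 cells. The values show only that these cells lie far below the IG2 median, and doublets with a cell low in Elane stay open. Carry-over from the pool of all cells would bring each gene at a like share of its mean. In the 17 cells with Gata1, 0 of 17 (upper limit 19.5%) had Elane at the share of Gata1, Elane reaching at most 7.01% of its mean. The count was 0 of 17 also for Mpo (at most 105%) and Prtn3 (43.7%), but 2 for Ctsg (223%, upper limit 36.4%) and 1 for Ms4a3 (164%). These cells were picked for Gata1, whose lowest share was 17.8% of its mean, and for lacking a state. The choice of cells thus largely set the counts, which show only that Gata1 there came without Elane at a like share. Carry-over from the pool is not decided by them, and carry-over from a single other cell stays open. Progenitors of these lineages inside the sort gate stay open as a candidate explanation. CD117 enrichment need not remove them, while how far the GMP sort does so was not examined. However, of the 8 mast cell and basophil genes 1, Hdc, is at a TPM of 30 in at least 50% of all cells and 4 at a TPM of 1. No biological explanation was tested, since the design has 1 group.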

How the results depend on the processing

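The runs on cells with a deposited state, without the cells in which 1 gene holds 5% of TPM, and at a TPM of 30 were chosen after the result was seen. Without those dominated cells 20 of 20 results kept their direction and call, as did 15 of 15 with a pseudocount of 10, which cannot move the ranks of single genes. Zbtb7b was found in 0% of cells at a TPM of 5 and 0% at 30, and list genes in at least 50% of cells numbered 38 at 30, by the stricter threshold itself. The cluster with most cells of the granule cluster held 72.9% of cells with 1000 variable genes, where it mixes states, and 59.4% of cells with a state. Irf8 with Gfi1 turned to -0.0117 in cells with a state and to -0.516 (p = 0.00626) in cells with either gene, where leaving out cells lacking both forces a negative value. Regression on genes detected and label number left 3 of 8 list pairs, with granule and S phase at 0.0658, granule and G2/M at -0.0508, monocyte and dendritic at -0.0760, and S phase and G2/M at -0.226 (adjusted p = 0.0554; r -0.269, adjusted p = 0.0163, a reversed direction). Granule with monocyte moved to 0.273 and granule with stem scores to -0.449, which was -0.544 in cells with a state. In cells with a state, granule and G2/M gave 0.255, monocyte and dendritic -0.0176, and S phase and G2/M 0.0903. Regression moved the genes called to 275 for Irf8, 48 for Gfi1, 141 for Elane, 52 for Mki67 and 0 for Cd34. The 275 are not independent evidence, since Irf8 is listed at 0 in 87 cells and its residual follows genes detected (rho -0.605). The same limit may hold for the 48 of Gfi1, detected in 21 cells, for which it was not computed. Cells with a state gave 36 for Gfi1, 860 for Elane, 17 for Mki67 and 0 for Cd34, from 69 cells. A filter of 50% of cells, which tests fewer genes, gave 67 for Gfi1, 680 for Elane, 138 for Mki67 and 1 for Cd34. Pearson's r gave 151 for Mki67 and 0 for Cd34, at least 2000 genes per cell gave 5 for Cd34, and genes in at least 3 cells gave 0 for Cd34. Intermediate events numbered 6041 with values in at least 10 cells, 600 with at least 40, and 1015 with bounds of 0.2 and 0.8, as these settings admit more or fewer events. Where no reason is given, the cause was not tested. Of 56 named correlations, 34 kept their call under regression and 22 lost it, 45 and 11 with Pearson's r. In cells with a state 18 of 55 lost it, with genes in at least 3 cells 9 of 56, with at least 2000 genes 2, and without dominated cells 1, and 0 changed sign under these settings. No paired analysis was possible because the cells form 1 group without replicate numbers. Unknown depth limits what a value of 0 or a single PSI can say.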

Other observations

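The tests of low values of abundant genes were chosen only after the result was seen, while those of PSI were written down before. In 6 cells a single gene held at least 5% of TPM. The eosinophil granule gene Prg2 reached a TPM of 300104 in cell 81 and 238281 in cell 16, which is 30.01% and 23.8% of all TPM. Prss34, a basophil and mast cell protease gene, reached 62985 in cell 56 and 59627 in cell 76, Anxa1 131293 in cell 83, which also had Prg2 at 81921 (8.19% of TPM) and the eosinophil genes Ear2 at 18886 and Ear6 at 5648, and the neutrophil gene S100a9 78119 in cell 94. Of these cells only cell 94 has a deposited state, Multi-Lin-1. Few genes were detected in them: 1019 in cell 83, the lowest of all cells, 1539 in cell 16 and 2009 in cell 94. Cells 76, 81 and 56 had 2431, 2477 and 2818, against a median of 3353 over all cells. These shares of TPM therefore come from sparse cells and are uncertain as levels of the genes.

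S phase genes were detected widely, 13 of 19 in at least 50% of cells, with Tyms in 94.8% and Pcna in 77.1%. Of 20 G2/M genes 3 were, with Top2a in 57.3%. The S phase score was 5.21 ± 1.41 (SD over cells) in proNeu-1, 4.90 ± 1.49 in IG2, 3.63 ± 1.74 in Multi-Lin-1 and 2.44 ± 1.69 in cells without a state, in the same order as the median genes detected (4127.5, 3940, 2950 and 2613), so the score cannot be told apart from genes detected. Of 12 immediate early and stress genes 8 reached 50% of cells, led by Hsp90aa1 (97.9%), Jun (83.3%) and Ier2 (76%), and of 12 interferon response genes 0. Highest on average were Actb (13.53), Eef1a1 (13.08), Ubb (13.05), Rps18 (12.72), Gpx1 (12.66), Rpl41 (12.63), Rps19 (12.60), Rpl32 (12.36), Rps14 (12.33) and Rpl13 (12.31).

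Cells that seem to lack an abundant gene often list it at a low level, as Elane in 41 cells under a TPM of 20. Transcripts shared between cells in proportion to their amount may add to this: over 15 genes the low level gave rho 0.411 with the mean TPM (permutation p = 0.130), and 0.314 without the 2 farthest genes, which leaves it undecided, as genes are few and not independent. If every cell held an equal share of pooled transcripts, Prg2 should be above 0 in nearly all cells under that level, as Elane was. Prg2 was listed at 0 in 57 of 84 such cells (67.9%, 56.8 to 77.6%), against 0 of 41 for Elane. However, Prg2 was at a TPM of 100 or more in only 5 cells, against 52 for Elane, and reads per cell are unknown. The share of Prg2 in a pool is therefore unknown, and its zeros do not decide the question.

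With values in at least 20 cells, intermediate PSI means were made mostly of values near 0 and near 1 (80.9% of events). With at least 40 cells this held for 53.3% of events. Few junction reads per cell would give such values. Of 2123 events 1050 had more values between the bounds in the upper part of cells by level of the gene, 710 fewer and 363 as many. So 59.7% of those that differed had more (exact sign test p = 5.2516e-16, over events that are not independent). The difference was small, with a mean share of 15.4% in the upper and 11.5% in the lower part. Of 1691 events, 1388 (82.1%, 80.2 to 83.9%) stayed intermediate within IG2, so for these a mixture of states is not needed to give an intermediate mean. The IG2 cells are a part of the cells by which the events were picked, and the interval counts events as independent. States were not compared, and their levels can differ, as in Srsf7 skipping with 0.645 in IG2 and 0.306 without a state. Different isoforms in different states are therefore not decided. Junction read counts per cell were not analysed here, so a true on or off choice of isoform in single cells stays open.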
